A study of Homo sapiens with 6 samples.

How the data were processed

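RNA from BJ1 cells, a line of human foreskin fibroblasts, was measured 72 h after transfection with 50 nM of a miR-29a mimic or of a control oligonucleotide named miR-Ctr. There were 3 samples in each group and 1 array per sample. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was amplified into Cy3-labelled cRNA, so each array has 1 colour.

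The spot intensities, in the processed signal column, were made by the authors with Agilent Feature Extraction 10.7.3.1, which subtracted and detrended the background of each array without scaling arrays to each other, per the file headers. The same files hold the raw mean and local background intensities and the flags for outlying, saturated and well-above-background spots, per the file headers. The deposited value table holds log2 values for 41000 probes. Within each array they ranked the probes as the processed signal did (Spearman correlation 1 on every array), and they lay a median of 0.010 to 0.020 log2 from a quantile normalization of that signal made here. Its columns have medians of 6.67, 6.65 and 6.62 in the controls and 6.66, 6.66 and 6.66 in the miR-29a samples. The submitters' processing notes name limma without a version, and whether they used it for this table is not given in the sources used here. The scale is therefore read from the values; no gene was centred and no direction is involved.

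The main values were log2 of the processed signal minus the 75th percentile of each array over its non-control probes. Control spots (1639 of 45015 per array) and outlier spots (63 to 322 per array) were left out, and spots of 1 probe were averaged. No non-control spot was saturated on any array (0 spots). Probes had to be well above background on at least 3 of the 6 arrays, which left 27048 probes. A gene was represented by its probe of highest mean over the 6 arrays. Of the 41000 probes, 28139 were named through an accession in RefSeq genes of GRCh38.p14, 2436 through the current symbol and 349 through an older symbol, and 10076 matched none. No coordinate was taken from that table. This gave 14316 genes, of which 14111 had a value on every array. Probe positions are those of the array annotation, on hg19.

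Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 differences are miR-29a minus miR-Ctr. Gene lists, 31 in all with 663 genes, of which 577 were kept, were fixed before the data were examined, as were the groups, the main design and the alternatives listed here. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the 31 lists, and again with the correlation estimated and with fry. Members were also adjusted over the list alone. A list score for an array is the median over the list of each gene's deviation from its mean over the 6 arrays. With 3 against 3 arrays the exact permutation test of a score cannot give a p under 0.1.

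The genes named in the text follow a rule with 3 parts. The first takes the genes of largest change past the threshold in all-gene adjustment with groups that do not overlap; 0 genes met it. The second is a fixed set of TET, DNMT, collagen, Wnt and reported target genes. The last takes up to 4 members of each list with the smallest p. Together they cover 126 measured genes, 125 of them tabulated, and the text gives some of these as examples; TET3, of the fixed set, was not kept by the filter. Other members named here passed the adjustment over their list alone, and any further gene is said to have been chosen after its values were seen. Of the 125, 46 had several kept probes, and the probes of 5 differed in sign: DNMT3A, GSK3B, CTNNB1, MCL1 and FZD5. A gene not well above background on any array of a group has only a bound there, the mean of the other group against, per array, the higher of its own value and the lowest value of a probe well above background.

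Slides and scan days coincided, and the arrays lay on 4 slides. The slide was tried as a fixed block, whose treatment estimate rests on the pair of arrays on slide 1 with 1 residual degree of freedom, and as a random block. Other alternatives were quantile or median scaling, normexp background correction (offset 50), the deposited value table, no filter or a filter on all 6 arrays, the mean of a gene's probes, every probe tested, eBayes with trend and robust, array quality weights, a replicate block, a fold of at least 1.5, each array left out in turn, and the arrays of slide 1 alone. Control replicate 3 left out with an estimated correlation was chosen after seeing the data. Samples with the same replicate number are not said to share a culture or day. On simulated data with the spread of these 14111 genes, the test recovered 19.3%, 60.0%, 82.0% and 91.3% of genes changed by 1, 2, 3 and 4 log2. There were 5 to 9 false calls per run of 122 to 140 calls. These shares cannot be read as the power in the real data. There 0 genes passed, although OASL differed by 3.86 log2 and ADAM19 by -2.99 log2. A planned comparison of genes with and without a miR-29 site in the 3' untranslated region was not run, since no transcript sequences were given. The number of arrays limits the precision of every value.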

Results

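BJ1 cells, an established line of human foreskin fibroblasts, were transfected with a synthetic mimic of the microRNA miR-29a or with a control molecule, miR-Ctr, each at 50 nM, in order to look for targets of miR-29a. The series title places the question in reprogramming to pluripotency and names active DNA demethylation and Wnt signalling. Gene expression was measured 72 h later on 6 arrays, 3 per group. The labels do not say whether the 3 samples of a group were separate transfections, so the p-values measure only the spread between these samples, which may be technical. Slide 1 held control replicate 1 and miR-29a replicate 1, slides 2 and 3 held control replicates 2 and 3, and slide 4 held miR-29a replicates 2 and 3. Values within slide 1, 1 array against 1 and without a test, are therefore given beside many of the results.

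Between 60.3% (control replicate 3) and 68.5% (control replicate 2) of the 41000 probes were well above background, and the median spot was 6.02 to 7.08 times its local background. Control replicate 3 stood apart. Over 264 probes printed 10 times, the median coefficient of variation between spots was 33.8% on that array and 4.17% to 11.1% on the others. Its mean correlation with the other arrays across genes was 0.901, against 0.950 to 0.962 for the rest. The miR-29a replicates on slide 4 correlated at 0.993.

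**Figure D1:**
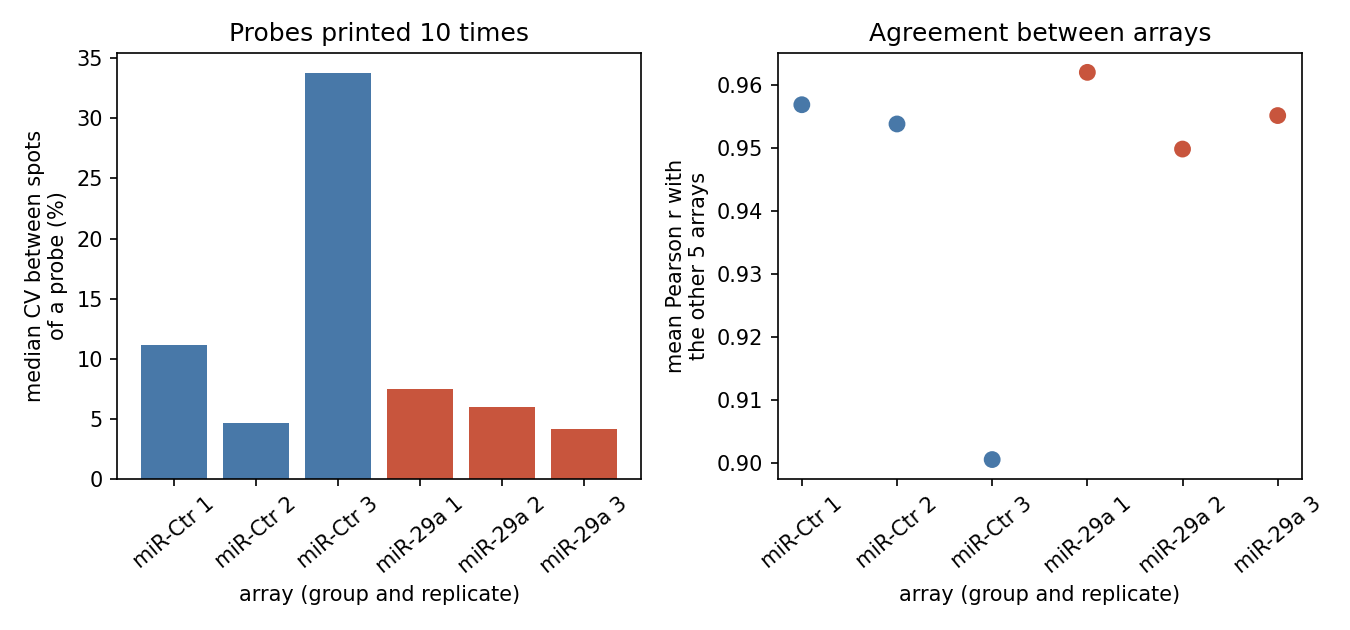
Quality of the 6 arrays, with controls in blue and miR-29a in red: the left panel shows bars of the median coefficient of variation (%) between the spots of 264 probes printed 10 times, and the right panel shows points of the mean Pearson correlation across genes with the other 5 arrays. Control replicate 3 has the highest variation (33.8%) and the lowest mean correlation (0.901).

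Collagen genes were lower and interferon response genes higher in the cells given miR-29a. Of 24 collagen genes, 9 fell and 15 did not pass, adjusted over the list alone, and of 34 interferon response genes 27 rose and 7 did not pass. Among genes fixed in advance, SPARC, TET1, TET2, DKK1 and CTNNBIP1 also fell, adjusted over their lists alone. No gene passed over all 14316 genes tested: limma called 0 higher and 0 lower, with a smallest adjusted p of 0.0749. At an unadjusted p under 0.05 there were 2597 genes, 1178 higher and 1419 lower, where 716 would be expected by chance. The 3 arrays of one group lay above all 3 of the other for 3955 genes (27.6%), against 10% by chance. The count of calls was not 0 in 4 alternatives: 710 higher and 378 lower with the slide as a fixed block, 671 higher and 675 lower with the slide as a random block, 2112 higher and 1864 lower with array quality weights, and 66 higher and 79 lower without miR-29a replicate 1. Scaling to the median moved the median of all genes by -0.12 log2 and the share higher among genes with p under 0.05 from 45.4% to 30.1%.

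Collagens, the structural proteins of the extracellular matrix and textbook targets of miR-29, had a median change of -0.66 log2 (1.58-fold lower). The fibrillar collagen genes COL3A1, COL1A1 and COL1A2 fell by 2.01 ± 0.17, 1.78 ± 0.17 and 1.98 ± 0.27 log2 (± SE), and COL4A1, of basement membranes, fell by 2.45 ± 0.52, all adjusted over the list alone. COL12A1, COL5A3, COL6A3, COL4A2 and COL11A1 also fell. The level of COL3A1 relative to the array's 75th percentile was 3.45 ± 0.11 log2 (SD, n = 3) in controls and 1.44 ± 0.14 (SD, n = 3) with miR-29a, from a probe on chromosome 2 between positions 189875071 and 189875412 of hg19. That of COL1A1, measured on chromosome 17 at 48261565 to 48261626, was 4.72 ± 0.12 and 2.94 ± 0.13 log2 (SD, n = 3). A further probe of COL1A2 differed by -0.39. Of the 24 genes 21 were lower, and in 13 every miR-29a array lay below every control. The list was called by camera (adjusted p = 1.1e-07), and the call was lost with an estimated correlation (adjusted p = 0.76 with an estimated correlation). The list median was -0.72 within slide 1, where 18 of 24 were lower, and -0.71 with the slide as a random block; fibroblast markers had a median of -0.08.

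Among other matrix genes, 6 of 39 fell, adjusted over the list alone, and 33 did not pass. The 6 were FBN1 and FBN2 (fibrillins), which fell by 1.77 ± 0.33 and 1.41 ± 0.29 log2, SPARC, a collagen-binding matrix protein, which fell by 1.56 ± 0.29, and LAMC1, LAMA2 and NID1, components of basement membranes. Elastin (ELN) differed by -0.97 ± 0.33 and did not pass, its 4 probes ranging from -2.71 to -0.72. As a list these genes were not called (adjusted p = 0.34), with a median of 0.0050 and a mean of -0.15, which differ in sign. The median was -0.085 within slide 1 and -0.11 with the slide as a random block, which called the list (adjusted p = 0.030, from 0.030 to 0.81 over the alternatives). An estimated correlation, not run with that block, did not call it (adjusted p = 0.76). Of 26 genes of collagen processing, LOXL2, a lysyl oxidase that cross-links collagen, and P3H2, a prolyl hydroxylase, fell by 2.10 ± 0.33 and 1.17 ± 0.22, and 24 did not pass. The list median was -0.33 (adjusted p = 0.22), against -0.10 within slide 1 and -0.075 with the slide as a random block. Of 24 matrix proteases and inhibitors, ADAM19, ADAMTS5, ADAMTS1, ADAMTS12, MMP15 and MMP16 fell. ADAM19, a membrane protease, fell by 2.99 ± 0.39, with -2.05 within slide 1 and -1.63 by a further probe, and ADAMTS5, which cleaves aggrecan, fell by 1.75 ± 0.27. ADAMTS4 rose by 0.98 ± 0.28 and 17 did not pass, adjusted over the list alone; the list median was -0.11 (adjusted p = 0.34).

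**Figure D2:**
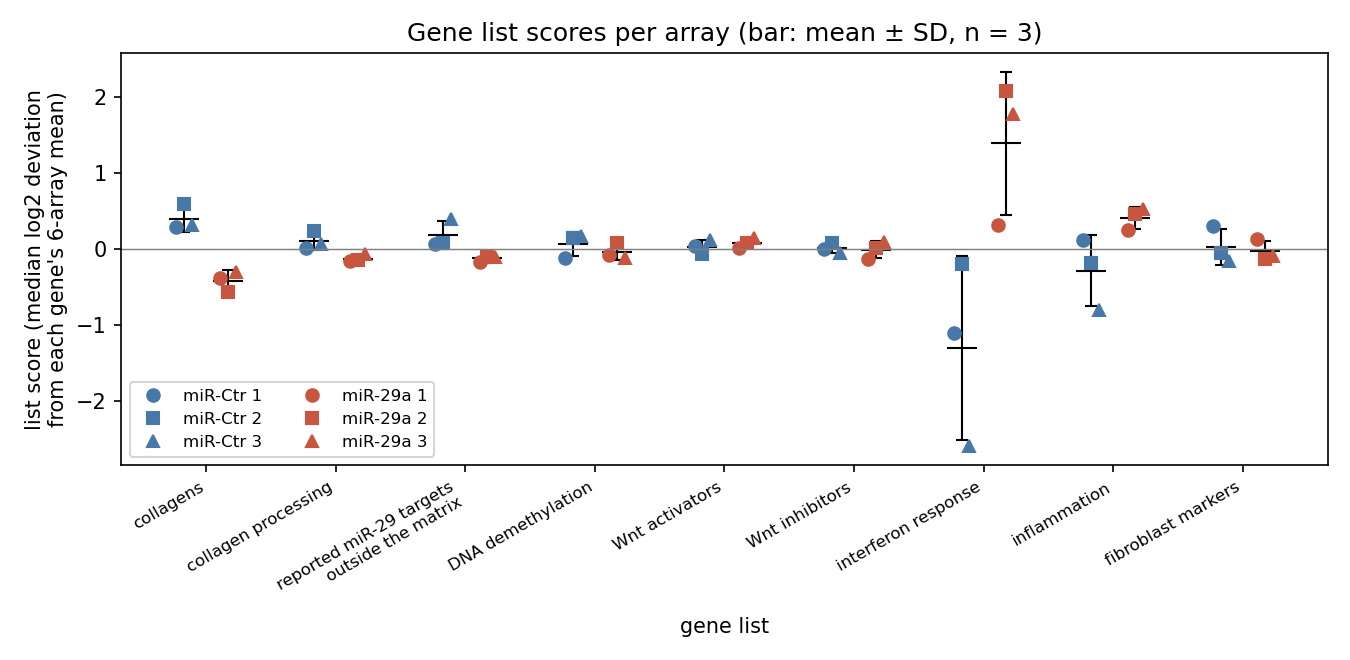
List scores on each of the 6 arrays for 9 gene lists, where the vertical axis is the median log2 deviation of the list's genes from their 6-array means, points are arrays (controls blue, miR-29a red) and bars show the mean ± SD of 3 arrays. The collagen scores are 0.28 to 0.59 in controls and -0.57 to -0.30 with miR-29a, and the interferon scores are -2.59 to -0.20 and 0.32 to 2.08.

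TET1 and TET2, which oxidise 5-methylcytosine and so start active demethylation, fell, adjusted over the DNA demethylation list alone; the other 14 measured members did not pass. TET2 fell by 1.09 ± 0.25 log2, with a value of -0.63 within slide 1, and its further probe differed by -0.29. TET1 fell by 0.72 ± 0.17, with a value of -0.80 within slide 1. TET1 was well above background on all 3 control arrays and on 0 miR-29a arrays, so it was at least 1.52-fold lower. Their probes lie on hg19 chromosome 10 at 70453536 to 70453595 (TET1) and chromosome 4 at 106200570 to 106200629 (TET2). TDG, the glycosylase that removes the oxidised base, differed by -0.63 ± 0.20 (adjusted p = 0.093 over the list alone), with 3 probes between -0.69 and -0.55. TET3 was on the array but not kept by the filter on dim probes. The list was not called (adjusted p = 0.63). Its median was -0.07 (0.0032 within slide 1) and its mean 0.15, with IDH1 at 4.23 ± 1.69, where the controls had an SD of 3.61 log2.

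None of the 13 measured DNA methylation genes passed over their list alone (0 genes), and the list median was 0.03 (adjusted p = 0.98), against -0.17 within slide 1 and -0.095 with median scaling. The methyltransferase genes DNMT1, DNMT3A and DNMT3B differed by 0.37 ± 0.46, -0.12 ± 0.21 and -0.43 ± 0.36 log2. DNMT1 was at -0.15 without control replicate 3. The 2 probes of DNMT3A differed in sign (-0.12 and 0.43).

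Genes of the Wnt pathway went both ways. Among 23 Wnt inhibitors, 3 fell and 2 rose, adjusted over the list alone, and 18 did not pass. CTNNBIP1, which keeps beta-catenin from its DNA-binding partners, fell by 1.09 ± 0.25 log2, DKK1, a secreted antagonist of the Wnt receptor complex, by 0.88 ± 0.21, and the corepressor gene TLE4 by 1.07 ± 0.26. TLE3, also a corepressor gene, and KREMEN1, a receptor for DKK proteins, rose by 1.57 ± 0.30 and 1.65 ± 0.37, and a further probe of TLE3 differed by 0.37. GSK3B, the kinase that marks beta-catenin for degradation, differed by -0.76 ± 0.22 (adjusted p = 0.052 over the list alone), and its other probe by 0.13. KREMEN2 differed by -0.11 ± 0.34. Of 30 Wnt activators, WNT5A, FZD4 and FZD5, a ligand and a pair of receptors, fell by 1.12 ± 0.16, 1.09 ± 0.22 and 0.80 ± 0.18, although further probes of FZD4 and FZD5 differed by -0.28 and 0.72. TCF7 and BCL9, which act in beta-catenin's transcription complex, rose by 1.62 ± 0.36 and 1.32 ± 0.34, and 25 did not pass. Within slide 1 TCF7 and BCL9 were at 0.64 and 0.38, and TLE3 and KREMEN1 at 0.92 and 0.76. Beta-catenin itself (CTNNB1) differed by 0.25 ± 0.22. Among 15 genes that respond to Wnt signalling, TCF7 rose, DKK1 fell and 13 did not pass, with a list median of 0.30 (adjusted p = 0.34), against 0.014 within slide 1 and 0.13 with the slide as a random block. Neither the inhibitors (median 0.12, adjusted p = 0.98) nor the activators (median 0.13, adjusted p = 0.98) were called. Their medians changed sign within slide 1 (-0.042 and -0.13), with the slide as a random block (-0.053 and -0.068), with normexp background correction (-0.12 and -0.046) and, for the inhibitors, with median scaling (-0.00395), and neither was called there.

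**Figure D3:**
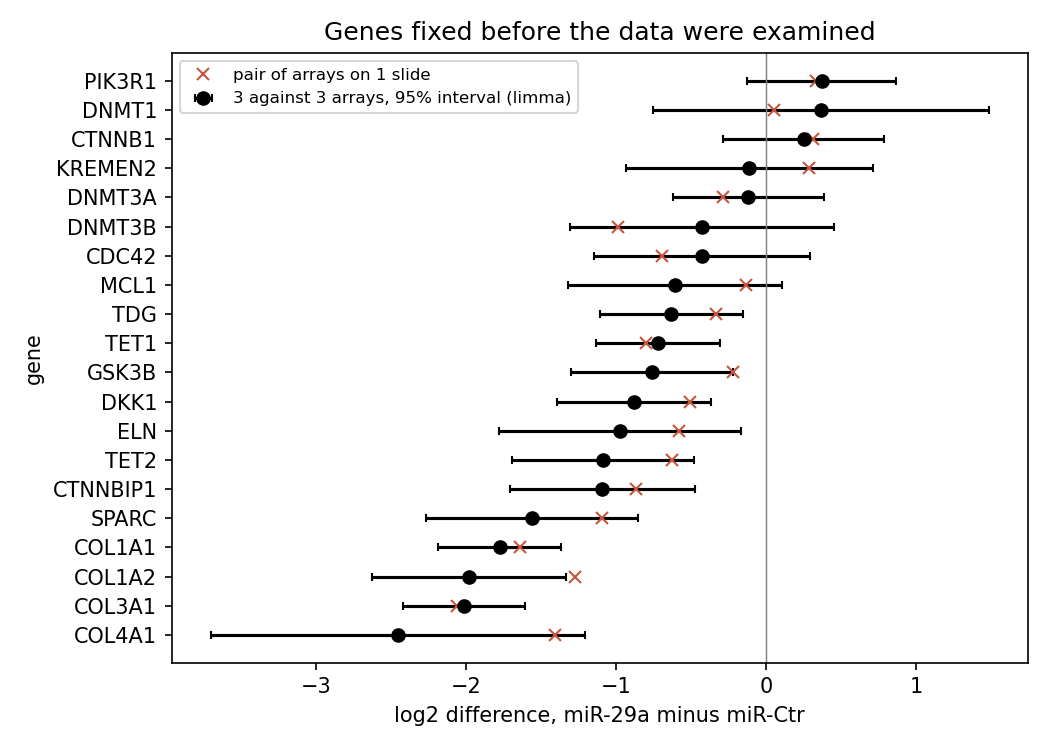
Log2 difference (miR-29a minus miR-Ctr, horizontal axis) of the 20 genes of the fixed set (vertical axis), where black points and bars are the limma estimate from 3 against 3 arrays with its 95% interval, and crosses are the pair of arrays on slide 1. The 4 collagen genes and SPARC have the lowest estimates, from -2.45 to -1.56, and their crosses lie between -2.06 and -1.09.

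Of 44 reported miR-29 targets outside the matrix, 6 fell, 1 rose and 37 did not pass, adjusted over the list alone. CDK6, a kinase of the G1 phase, fell by 2.37 ± 0.25 log2, with -1.76 within slide 1 and -1.33 by a further probe. BACE1, the beta-secretase, fell by 0.99 ± 0.16. The others that fell were TET1, TET2, CTNNBIP1 and DKK1, which are also members of the DNA demethylation and Wnt inhibitor lists. VEGFA, an angiogenic growth factor, rose by 1.07 ± 0.26. MCL1, CDC42 and PIK3R1 did not pass, at -0.61 ± 0.29, -0.43 ± 0.30 and 0.37 ± 0.20, and the 3 probes of MCL1 ranged from -0.61 to 1.68. The list median was -0.31 (camera adjusted p = 0.0025; adjusted p = 0.76 with an estimated correlation), with 32 of 44 genes lower, and it was -0.27 within slide 1 and -0.29 with the slide as a random block. The call ended without miR-29a replicate 1 (-0.30, adjusted p = 0.094), with the mean of a gene's probes (-0.16, adjusted p = 0.092) and with array quality weights (-0.21, adjusted p = 0.10); over the alternatives the adjusted p ranged from 2.04e-05 to 0.80.

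The interferon response genes had a median change of 2.79 log2, and all 34 were higher with miR-29a. IFIT2 and IFIT3, antiviral effectors, rose by 2.67 ± 0.41 and 2.95 ± 0.68 log2, adjusted over the list alone. OASL, related to the oligoadenylate synthetases, and RIGI, a sensor of viral RNA, rose by 3.86 ± 0.79 and 2.28 ± 0.48. Within slide 1 OASL and RIGI were at 1.76 and 1.04. OAS1, RSAD2, IFI44L, MX2 and MX1 rose by 4.12 to 5.10 log2. Camera called the list (adjusted p = 9.4e-16), and the call was lost with an estimated correlation (adjusted p = 0.76 with an estimated correlation), which was 0.834 between these genes. The scores were -1.10, -0.20 and -2.59 on control replicates 1, 2 and 3 and 0.32, 2.08 and 1.77 on miR-29a replicates 1, 2 and 3. The median was 1.29 within slide 1, where all 34 genes were higher, 1.53 with the slide as a random block (adjusted p = 5.0e-12) and 1.82 without control replicate 3 (adjusted p = 1.4e-12; adjusted p = 0.81 with an estimated correlation).

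Of 24 genes of inflammation, 0 passed over the list alone. CSF3, CXCL3 and CXCL8, a colony-stimulating factor and chemokines that attract neutrophils, were at 2.96 ± 0.69, 1.77 ± 0.44 and 1.97 ± 0.54 log2. Within slide 1 these genes were at 1.66, 0.42 and 0.65. The list median was 0.77 (camera adjusted p = 0.039; adjusted p = 0.76 with an estimated correlation). The median was -0.02 within slide 1 and 0.13 with the slide as a random block, and the call ended with either slide block. It also ended with the replicate block (adjusted p = 0.089), array quality weights (0.54, adjusted p = 0.36), the mean of a gene's probes (adjusted p = 0.065), no filter (0.46, adjusted p = 0.060) or a filter on all 6 arrays (0.63, adjusted p = 0.13), and without control replicate 3 (0.57, adjusted p = 0.22), miR-29a replicate 1 (0.90, adjusted p = 0.13) or miR-29a replicate 3 (0.68, adjusted p = 0.064). Over the alternatives the adjusted p ranged from 0.00095 to 0.81.

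In the other lists few members passed over the list alone, and none of these lists was called. In the p53 response, the DNA repair gene XPC and the stress gene SESN2 rose by 1.09 ± 0.19 and 1.91 ± 0.38 log2, TRIAP1 and TP53I3 fell by 1.41 ± 0.30 and 0.66 ± 0.15, and 23 of 27 did not pass (median 0.30, adjusted p = 0.11, and 0.15 within slide 1). In the cell cycle list MYBL2, a transcription factor of proliferating cells, fell by 1.74 ± 0.29 and 44 of 45 did not pass (median -0.20, adjusted p = 0.13, and -0.068 without control replicate 3). In the hypoxia list ADM fell by 0.86 ± 0.16, PFKFB4 and VEGFA rose, and 14 of 17 did not pass (median -0.28, adjusted p = 0.34). Among growth factors and receptors PDGFA fell by 1.54 ± 0.30 and 21 of 22 did not pass (median -0.16, adjusted p = 0.63). Among epithelial genes the tight junction gene CLDN1 fell by 2.70 ± 0.29 and 12 of 13 did not pass (median 0.14, mean -0.12, adjusted p = 0.71). No member passed in the lists of TGF-beta and myofibroblast genes (0 of 30, median -0.13, adjusted p = 0.58), mesenchymal genes (0 of 12, median 0.22, adjusted p = 0.71) and pluripotency (0 of 5, median 0.25, adjusted p = 0.71). Of the TGF-beta and myofibroblast genes 15 were lower and 15 higher. TGFB2 differed by -3.88 ± 0.88, with -1.53 within slide 1, and TGFBR1 by 0.89 ± 0.23 (each adjusted p = 0.074 over the list alone). None passed among BCL2 family genes (0 of 14, median -0.03, mean 0.06, adjusted p = 0.71) and microRNA machinery (0 of 13, median 0.11, mean -0.04, adjusted p = 0.81). The same held for the unfolded protein response (0 of 22, median -0.01, mean 0.21, adjusted p = 0.95), cholesterol synthesis (0 of 25, median 0.18, adjusted p = 0.41) and stress and immediate early genes (0 of 17, median -0.03, tested upward, adjusted p = 0.81). Housekeeping genes, of which 0 of 20 passed, had a median of 0.13 (adjusted p = 0.63), which turned to -0.10 with quantile scaling and -0.11 in the deposited value table. Within slide 1 the medians had the opposite sign for pluripotency (-0.32), mesenchymal (-0.15), epithelial (-0.043), microRNA machinery (-0.088), cholesterol synthesis (-0.074), hypoxia (0.12) and melanocyte genes (0.26). With normexp correction they did for pluripotency (-0.038), epithelial (-0.075), BCL2 family (0.10), microRNA machinery (-0.021), unfolded protein response (0.028), stress (0.13), endothelial (-0.042) and leukocyte genes (-0.0096).

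Markers of fibroblasts had a median of -0.08 and a mean of 0.04 (adjusted p = 0.995); NT5E, the ectonucleotidase CD73, rose by 1.15 ± 0.25 log2, its 3 probes ranging from 0.21 to 1.15, and 9 of 10 did not pass. Of markers of other cells that a skin culture could hold, none of 8 for keratinocytes (0 genes, median 0.46, adjusted p = 0.21) and none of 7 for endothelium (0 genes, median 0.43, adjusted p = 0.26) passed over the list alone. MITF, a transcription factor of melanocytes that other cells also express, fell by 1.00 ± 0.23, its 3 probes ranging from -1.03 to -0.23, and the other 3 melanocyte markers did not pass (median -0.34, adjusted p = 0.41). LAPTM5, a lysosomal protein of leukocytes, rose by 1.64 ± 0.37 and was at least 2.58-fold higher, being well above background on 0 control arrays and 3 miR-29a arrays; the other 5 leukocyte markers did not pass (median 0.15, adjusted p = 0.58). With estimated correlations or with fry's directional test, 0 of the 31 lists were called, with smallest adjusted p of 0.76 and 0.060. Fry's test of changes in either direction, which shows no shift of a list, was not used for calls. Its smallest adjusted p was 0.0025 (collagens), but it did not single them out. Lists such as housekeeping genes (0.026) and fibroblast markers (0.029) were also under 0.05 in that test.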

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

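Signal appeared in probes that match no gene and so enter no comparison of genes or lists; of the 27048 kept probes, these included, 0 passed when each was tested on its own (limma, 4377 at an unadjusted p under 0.05). Of 10076 probes matched to no gene, 12 were well above background on all 3 miR-29a arrays and on 0 of the control arrays. The opposite pattern was found in 28 such probes. Among the 30924 probes with a gene the counts were 43 and 81, so neither pattern was particular to probes without a gene. No explanation was tested for these probes. Groups of 3 arrays are too small for the test of single outlying samples, so no sample was screened that way.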

How the results depend on the processing

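Leaving out control replicate 3 together with an estimated correlation was chosen after the data had been examined; the other alternatives were planned. Where no reason is given, the cause was not tested. The collagens kept their direction under every alternative run (medians -0.81 to -0.59) and lost their call with the estimated correlation and with fry. The interferon response genes also kept theirs (1.29 to 3.39) and lost their call in the same tests, and the reported targets stayed lower (-0.44 to -0.16). Of the values of named genes under the alternatives, 2183 kept direction and side of the threshold, 191 passed it, 83 moved without a test and 30 reversed. DNA demethylation, Wnt inhibitors and Wnt activators were counted with the called lists, where 121 values stayed, 24 lost a call, 13 reversed and 3 moved. For the remaining lists, none called in the main test, 460 stayed, 73 reversed, 13 moved and 6 became calls. The 6 were collagen processing and cell cycle with no filter, cell cycle without control replicate 2, TGF-beta genes with every probe tested, and the p53 response with every probe tested and with normexp; the reversed matrix list was also called with the slide as a random block. The planned tests of 3' untranslated region sites were not run, for lack of transcript sequences. The within-slide comparison gives no count of genes. The signal, 6.02 to 7.08 times local background, limits what dim probes such as those of TET1 can show.

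Gene counts rose from 0 to 3976 with array quality weights, 1088 with the slide as a fixed block and 1346 with it as a random block, and leaving out 1 array gave 0 to 145. The fixed and random blocks shared 732 genes, and the weights shared 735 and 1112 with them. Weights of 6.63 and 2.96 went to miR-29a replicates 3 and 2, which share a slide, and 0.160 to control replicate 3. The replicate block called 0 genes (1081 higher and 1151 lower at an unadjusted p under 0.05 by limma). Every probe tested on its own gave 0 calls (limma, 4377 probes at an unadjusted p under 0.05).

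Medians with the estimated correlation and with fry are those of the main test: collagens -0.66 (adjusted p = 0.76 and 0.060), reported targets -0.31 (0.76 and 0.10), interferon response 2.79 (0.76 and 0.16) and inflammation 0.77 (0.76 and 0.36). The shared 0.76 is a tie made by the adjustment. Before it, camera with an estimated correlation gave p = 0.030, 0.12, 0.14 and 0.30 for these lists in that order. With control replicate 3 left out and an estimated correlation, the medians were -0.77 for collagens, -0.21 for reported targets, 1.82 for interferon response, 0.57 for inflammation, 0.065 for the unfolded protein response and 0.10 for stress genes; none was called (adjusted p = 0.80 to 0.81 for the first 4).

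With array quality weights, reported targets were at -0.21, mesenchymal genes at -0.0069, epithelial at -0.15, TGF-beta at 0.048, growth factors at 0.028, inflammation at 0.54, unfolded protein response at 0.24, stress at 0.12, KREMEN2 at 0.10, MYC at 0.069 and KRT14 at -0.051. With the slide as a fixed block, which rests on the slide 1 pair, other matrix genes were at -0.085, DNA demethylation at 0.0032, DNA methylation at -0.17, Wnt activators at -0.13, Wnt inhibitors at -0.042, pluripotency at -0.32 and mesenchymal genes at -0.15. Epithelial genes were at -0.043, microRNA machinery at -0.088, inflammation at -0.017, cholesterol synthesis at -0.074, hypoxia at 0.12 and melanocyte markers at 0.26. Single genes there were KREMEN2 at 0.29, UHRF1 at -0.20, KLF4 at -0.22, ZEB1 at 0.044, CRB3 at 0.65, SLC2A1 at 0.16, PDGFRA at -0.052 and CD14 at 0.14. Within that slide alone, Wnt activators were at -0.13, Wnt inhibitors at -0.042, interferon response at 1.29 and inflammation at -0.017. With the slide as a random block, other matrix genes were at -0.11, Wnt activators at -0.068, Wnt inhibitors at -0.053, pluripotency at -0.30, mesenchymal at -0.13, epithelial at -0.017 and microRNA machinery at -0.088. Inflammation was at 0.13, cholesterol synthesis at -0.065, melanocyte markers at 0.14, KREMEN2 at 0.21, KLF4 at -0.13, CRB3 at 0.33 and CD14 at 0.060. With the replicate block the inflammation call ended (0.77).

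With quantile scaling, other matrix genes were at -0.048, epithelial at -0.036 and housekeeping at -0.096. With median scaling, other matrix genes were at -0.12, DNA methylation at -0.095, Wnt inhibitors at -0.00395 and microRNA machinery at -0.00983; this scaling lowers all genes, by its construction. In the deposited value table, other matrix genes were at -0.049, epithelial at -0.021, housekeeping at -0.11, VIM at -0.042 and ACTB at -0.11. With normexp, other matrix genes were at -0.030, DNA methylation at -0.073, Wnt activators at -0.046, Wnt inhibitors at -0.12, pluripotency at -0.038, epithelial at -0.075, BCL2 family at 0.10 and microRNA machinery at -0.021. The unfolded protein response was at 0.028, stress at 0.13, endothelial markers at -0.042, leukocyte markers at -0.0096, ESAM at -0.071, VWF at -0.17, CLDN5 at -0.039 and ROBO4 at -0.042.

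With every probe tested, epithelial genes were at -0.059, BCL2 family at 0.050, stress at 0.058 and fibroblast markers at 0.063. With the mean of a gene's probes, reported targets were at -0.16, inflammation at 0.77, stress at 0.22, DNMT3A at 0.15 and MCL1 at 0.22. With no filter, matrix proteases were at 0.070, DNA demethylation at 0.041 and inflammation at 0.46. With probes above background on all 6 arrays, other matrix genes were at -0.020, epithelial at -0.21 and inflammation at 0.63.

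Leaving out each array in turn gave ranges of -0.086 to 0.014 for other matrix genes, -0.16 to 0.15 for proteases, -0.41 to -0.21 for reported targets, -0.21 to 0.045 for DNA demethylation, -0.092 to 0.086 for DNA methylation and -0.081 to 0.21 for epithelial genes. They were -0.16 to 0.028 for TGF-beta, -0.20 to 0.12 for BCL2 family, -0.036 to 0.19 for microRNA machinery, 0.57 to 1.02 for inflammation, -0.14 to 0.065 for the unfolded protein response, -0.22 to 0.15 for stress and -0.23 to 0.028 for fibroblast markers. Without a change of sign they were 0.030 to 0.28 for pluripotency, -0.24 to -0.061 for growth factors, 0.034 to 0.19 for housekeeping genes and -0.58 to -0.22 for melanocyte markers. The same held for Wnt inhibitors (0.015 to 0.14), Wnt activators (0.039 to 0.20) and hypoxia (-0.37 to -0.17). It also held for cholesterol synthesis (0.089 to 0.24) and mesenchymal genes (0.14 to 0.38). Single genes ranged from -0.15 to 0.77 (DNMT1), -0.26 to 0.019 (DNMT3A), -0.33 to 0.27 (KREMEN2), -0.053 to 2.73 (UHRF1), -1.18 to 0.10 (ESRRB), -0.14 to 0.99 (DCT) and -0.092 to 0.50 (PMEL). DNMT1, DNMT3A, KREMEN2 and UHRF1 each changed sign without control replicate 3.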

Other observations

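The tests of the slide, of control replicate 3 alone, of the fibroblast share and of spot noise were chosen only after the results they address had been seen. That of the slide replaced others that could not separate the slide from variation between samples, and it does so only in part. The tests of the splits, the seed word, neighbouring spots and probe pairs were set before. The margin asked of the probe pairs was the exception, chosen after their value was seen. The genes of the next paragraph were chosen after their values were seen, from among those with the smallest p over all genes. No rule fixed the choice, and others with p as small are not named. None passed the threshold (limma, 2597 genes at an unadjusted p under 0.05).

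NANOS1, a translational repressor of germ cells, was well above background on 3 control arrays and 0 miR-29a arrays and was at least 1.60-fold lower (adjusted p = 0.0749). TESMIN and ADAM32, genes of the testis, and APOBEC3H, a cytidine deaminase that restricts viruses, had the opposite pattern and were at least 2.08-fold, 1.81-fold and 3.64-fold higher. CSF1R, the receptor for macrophage colony-stimulating factor, was at 2.04 ± 0.23 log2 and 1.65 within slide 1, and PKIA, an inhibitor of protein kinase A, at 2.14 ± 0.25 and 2.18. RRAD and INPP5D, a small GTPase and an inositol phosphatase, were at 2.60 ± 0.35 and 3.11 ± 0.43. PPIC, CBX6, PRMT6 and AHR were at -2.11 ± 0.26, -1.64 ± 0.21, -1.83 ± 0.24 and -1.68 ± 0.23, where CBX6 is a Polycomb protein, PRMT6 an arginine methyltransferase and AHR the aryl hydrocarbon receptor. In each of these genes all 3 arrays of one group lay above all 3 of the other. That adds no support, since a choice by small p favours such genes. Over all genes the share was 27.6%, against 10% by chance.

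Collagen genes were lower with miR-29a. A slide difference as the whole cause is argued against by slide 1 alone, with 1 array against 1. There the median was -0.72 and 18 of the 24 genes were lower, but such a pair cannot measure variation between samples. With the slide as a random block, all of whose 1346 calls had that pair's sign, the median was -0.71. Camera called the list there (adjusted p = 1.9e-11), and 12 of the 24 genes passed over all genes. The correlation between arrays of a slide was estimated at 0.90 for that block. Its estimate therefore leans on the slide 1 pair and is not independent of it, and the shared signs add no support. The spread rests largely on the pair of arrays on slide 4. In the main test the call was lost with an estimated inter-gene correlation (adjusted p = 0.76), which was not run with the slide blocks. A smaller share of fibroblasts as the whole cause is argued against by 10 fibroblast markers, 6 lower and 4 higher. Their median of -0.08 had a 95% interval from -0.43 (bootstrap over genes), above the collagens' -0.66. Without control replicate 3 it was from -0.45, against -0.77. That interval measures the spread between markers, not between samples, and the collagens' median was taken as fixed. Of these markers 2 are also reported miR-29 targets. A smaller share would need markers of other cells to be higher, as 7 of 8 keratinocyte and 6 of 7 endothelial markers were (medians 0.46 and 0.43). None of them passed over its list alone, and some were dim. VWF, ESAM and KRT17 were well above background on 1, 2 and 2 control arrays. In an established fibroblast line such markers do not by themselves show other cells. Within slide 1 the keratinocyte and endothelial medians were 0.33 and 0.20, and with normexp the endothelial median was -0.042. Action of the mimic through its seed may contribute: among 11878 words of 7 bases in the probes of other genes, the seed match TGGTGCT ranked 3 from the lowest (percent rank 0.0253), and its 92 genes had a median of -0.27 log2 against 0.04 without it. Within slide 1 these medians were -0.24 and -0.0073. The words ranked above it, ATGGTGC and GGTGCTT (z = -6.36 and -5.60), overlap the same site. The next word, TCGAAGG, does not, yet its shift statistic was nearly as low as that of TGGTGCT (z = -4.82 against -4.88, in 22 genes). A further seed match, GGTGCTA, ranked 54. The probes cover only part of each transcript. Action through the seed remains a hypothesis, since the words do not show which genes changed directly and sites in the 3' untranslated region were not tested.

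Interferon response genes were higher with miR-29a. Control replicate 3 alone is argued against. Without it the median fell from 2.79 but was still 1.82 (camera adjusted p = 1.4e-12, and 0.81 with an estimated correlation). A slide difference as the whole cause is argued against by slide 1 alone, with 1 array against 1. There the median was 1.29 and all 34 genes were higher, but such a pair cannot measure variation between samples. With the slide as a random block, all of whose 1346 calls had that pair's sign, the median was 1.53. Camera called the list there (adjusted p = 5.0e-12) at an inter-gene correlation of 0.01, and 12 of the 34 genes passed over all genes. The correlation estimated in the main test was 0.834, and an estimated correlation was not run with the slide blocks. The medians of 1.29 and 1.53 are below the 2.79 of the main test. For miR-29a replicates 2 and 3 the slide and the mimic cannot be told apart, as their slide held 0 control arrays. A response to the mimic molecule apart from its targets stays open and untested, since only 1 mimic and 1 control molecule were used.

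Control replicate 3 stood apart from the other arrays. Spot-level noise may account for part of this, its coefficient of variation between spots of a probe being 3.03 times the next highest. Uneven hybridization stays open, with a correlation between neighbouring spots that was 0.0624 above that of the next control, between the bounds set for it. A different RNA content stays open too: the correlation between 2 probes of a gene, across genes, was 0.184 ± 0.0139 (SE), against 0.210 and 0.246 in the other controls, and lay under its bound of 0.2 by more than 1 SE but within a 95% margin. That bound made no allowance for spot noise, which lowers such a correlation whatever the RNA content, and the array's interferon score (-2.59, against -1.10 and -0.20) was also apart.

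The 6 arrays can be split in 10 ways into 3 against 3, so no share under 0.1 is possible and the splits are too few for a share under 0.05. For the number of genes, 10 of the 10 splits gave as many, the real split calling 0 (limma, 2597 genes at an unadjusted p under 0.05) and the highest of the others 0. For the camera p of the collagens 1 split, the real one, was as small (7.01e-09, next 3.39e-07). The same held, with 1 split each, for the reported targets (0.000242, next 0.000508) and DNA demethylation (0.365, next 0.393). For the interferon response it was also 1 split (3.04e-17, next 2.12e-16); the next split sets slides 1 and 3 against slides 2 and 4 and so follows the slides, and the median within slide 1 was 1.29. For inflammation 5 splits were as small (0.00501, smallest other 8.15e-06), and for Wnt inhibitors and activators 9 each (0.945 and 0.919, smallest others 0.514 and 0.0920).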
